A study of Peromyscus maniculatus and Peromyscus polionotus and Peromyscus maniculatus x Peromyscus polionotus with 18 samples.

How the data were processed

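Whole-brain RNA of adult male *Peromyscus* mice was profiled in 18 libraries, 3 for each of 6 groups: *P. maniculatus*, *P. polionotus* and their F1 hybrids, each killed at the end of either a burrowing trial in a sand-filled enclosure or a control trial. Per the labels' protocols, animals were 50 to 80 days old, had been through 2 earlier trials in the enclosures and were assigned to a cohort at random, brains were dissected whole, and libraries were made from total RNA with a stranded poly(A) kit. Groups and replicate numbers were taken from the sample titles. The protocols speak of individual animals, and each library was treated as 1 animal. The labels write the hybrid cross with *P. maniculatus* first; whether that names the mother is not given in the sources used here.

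The 12 libraries of the parental species were deposited as a table of TPM, transcript abundances scaled to a common library total, made by the authors, with 20732 rows and column sums from 977912 to 983476. The 6 hybrid libraries were deposited as whole-number counts per gene and parental allele, with 11928 rows and a smallest count of 2 in any column, so genes with low counts had been removed. Per the submitters' processing notes, reads were aligned with STAR 2.4.2a. The genome build, the annotation, whether the species were aligned to the same reference, how reads were given to an allele and how TPM were computed are not given in the sources used here. Only reads that could be given to an allele are in the count table. 1 row of the TPM table names no gene and held 0.774% to 2.44% of the TPM of a library; it was left out. Spreadsheet software had turned the names of 27 rows of the TPM table and 19 rows of the count table into dates, and these rows were tested but not named. Symbols were matched without regard to case. A table of gene symbols for assembly GCF_049852395.1 HU_Pman_BW_mat_3.1 matched 17566 names (84.7%) of the TPM table and 10155 (85.1%) of the count table; it was used only to find genes on the X and genes that neighbour each other, and no coordinates are given because the build of the files is unknown.

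Depth could be read only from the count table: allele-assigned counts ranged from 11415175 to 53906964 per hybrid animal. Shares given for a single animal carry a 95% Wilson interval, which covers counting error only. TPM keep no depth, so the precision of the parental values is known only from the spread between libraries. At most 0.964% of genes held identical values in a pair of replicates, and Spearman correlations across genes within groups were 0.952 to 0.996.

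Parental libraries were tested with limma 3.58.1 (moderated statistics with a mean trend) in R 4.3.3 on log2(TPM + 1), for 14366 genes with a mean of at least 1 TPM. A model with 1 mean per group gave 7 contrasts, and the 12 libraries shared 1 estimate of the spread. Fold changes are on the log2(TPM + 1) scale, which understates changes of genes with low values. Hybrid counts summed over both alleles were tested between trials with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test). Allele counts were tested with the same edgeR test with each animal as a block, the sum of both alleles as the library size of both columns, and a minimum mean of 20 counts per animal; the allele by trial term was added for the interaction. Neither filter removed a gene from the count table. P-values of these gene tests measure spread between these animals. All gene tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a comparison, and a gene was called below an adjusted p of 0.05. A polionotus share is the percentage of a gene's allele-assigned counts on the polionotus allele. Errors after ± are SD between animals unless named SE.

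Before the data were examined, 50 lists of rodent brain genes were fixed from general knowledge, covering cell types, brain regions, transmitter systems, behaviour, stress responses and tissues a dissection can carry along. Lists with at least 5 tested members (46 in the parental table, 42 in the count table) were tested with limma camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, with fry and with Fisher's exact test of higher against lower called members. Camera at the preset correlation and Fisher's test take genes as the units, so their p-values do not measure spread between animals. None of the camera calls held with an estimated correlation in any of the 10 comparisons. Named genes were chosen by a rule fixed at the same time: per direction the 8 largest changes among called genes with a symbol, at least 5 TPM or 100 counts and no overlap between groups; where none passed, the 3 genes per direction with the smallest p, given as not passing; the 3 members with the smallest p from each list passing camera; 8 activity or glucocorticoid genes in each trial comparison and 10 neuropeptide, dopamine and striatal genes in each species or allele comparison. Of the genes the rule named, 143 gene and comparison pairs were followed through the alternatives; this subset was picked after their values were seen.

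The tests were checked on simulated data. TPM were simulated with each gene's residual SD, and counts with each gene's dispersion estimated from the real libraries. At a change of 0.5 log2 the species test recovered 86% of changed genes and at 1 log2 97%, over 14366 genes. For a response within 1 species these shares were 59% and 94% in *P. maniculatus* and 61% and 93% in *P. polionotus*, for the interaction 24% and 87%, and for the response averaged over both species 81% and 98%. In the hybrids, over 11928 genes, the trial test recovered 58% at 1 log2 and 98% at 2 log2. The allele test recovered 6.1% at 0.5, 60.3% at 1 and 92.4% at 2 log2, over 11922 genes, and the allele by trial test 2.9% at 1, 62.1% at 2 and 86.4% at 3 log2, over 11925 genes. Between 3.5% and 8.7% of the simulated calls were false. Between alleles only 66 to 68 genes were changed per effect size, and noise was drawn independently per gene. The real allele test called 6641 genes, 2084 of them over 1 log2, so the simulated shares need not hold for the real tests.

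Alternatives fixed at that time covered the pseudocount, the filters, quantile and median scaling, TMM per allele column, DESeq2 1.42.0, a binomial test per animal, a block on the replicate number, fits on only the groups compared, list members with a mean of at least 5 TPM or 100 counts, and leaving out each library in turn. Those added after the data were seen left out the polionotus control libraries with low hindbrain genes or the other pairs of that group, set species against alleles under other scalings, took the hindbrain list as a covariate, left out genes on the X or with over 95% of counts on 1 allele, or tested allele log ratios without a block. Explanations of some patterns were tested by gene order, correlation between libraries, exact permutation and other splits of the samples. P-values from gene order and for X linkage are over genes, and the binomial test per animal covers counting error only. Figures were drawn with matplotlib 3.10.9.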

Results

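The series profiled the brain transcriptome of males of deer mouse species that differ in how they dig. *P. polionotus*, the oldfield mouse, builds long burrows with an escape tunnel, and *P. maniculatus*, the deer mouse, builds short simple ones. Each of the 6 groups (species or F1 hybrid, after a burrowing or a control trial) held 3 libraries. The first principal component of the parental libraries held 68.3% of the variance and separated the species, with scores from -31.3 to -29.7 in *P. maniculatus* and from 28.7 to 34.6 in *P. polionotus*. The second component held 7.5%. On it maniculatus control replicate 3 (-20.5), polionotus burrowing replicate 3 (-15.5) and polionotus control replicate 2 (-12.6) lay apart from the other libraries (-1.6 to 13.2). These libraries came from both species and both trials. What set them apart was not tested, and the component was not part of the models. Between 14104 and 14392 genes per parental library had at least 1 TPM. MTRNR2L6, a humanin-like transcript, took 6.4% to 9.57% of TPM in *P. maniculatus* and 3.06% to 5.2% in *P. polionotus*. In the hybrids, allele-assigned counts were 11415175, 12595542 and 53906964 in the control animals and 26264699, 28994982 and 22510205 in the burrowing animals, of which 52.6% to 53.1% lay on the polionotus allele.

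The species comparison asks which brain genes differ between a complex and a simple burrower. Vasopressin (Avp), the peptide of hypothalamic neurons tied to social behaviour and water balance, was at 25.2 ± 7.24 TPM in *P. polionotus* and 78.1 ± 14 TPM in *P. maniculatus* (SD, n = 6 libraries each; log2 fold change -1.62, SE 0.16, adjusted p = 1.05e-05). Drd1 and Adora2a, receptors that mark output neurons of the striatum, went the other way. The dopamine receptor Drd1 was at 171 ± 10.4 against 95.4 ± 14.7 TPM (0.85, SE 0.09, adjusted p = 2.79e-05), and the adenosine receptor Adora2a at 37.9 ± 2.84 against 19.2 ± 4.01 TPM (0.96, SE 0.12, adjusted p = 8.66e-05). For these 3 genes no library of 1 species reached into the range of the other. Penk, the enkephalin precursor, was higher in *P. polionotus* by 0.42 (SE 0.09, adjusted p = 0.00314), and the dopamine transporter Slc6a3 by 0.33 (SE 0.1, adjusted p = 0.0148), which did not pass without polionotus control replicates 2 and 3, an alternative chosen after seeing the data (0.32, adjusted p = 0.0801). Values for Drd2 (0.1, SE 0.1), Oxt (0.32, SE 0.31), Tac1 (-0.04, SE 0.07) and Crh (-0.27, SE 0.12, adjusted p = 0.0825) did not pass, although Crh passed with quantile or median scaling (adjusted p = 0.0349 and 0.0464) and without polionotus burrowing replicate 2 or control replicate 2 (0.0454 and 0.0415).

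**Figure D1:**
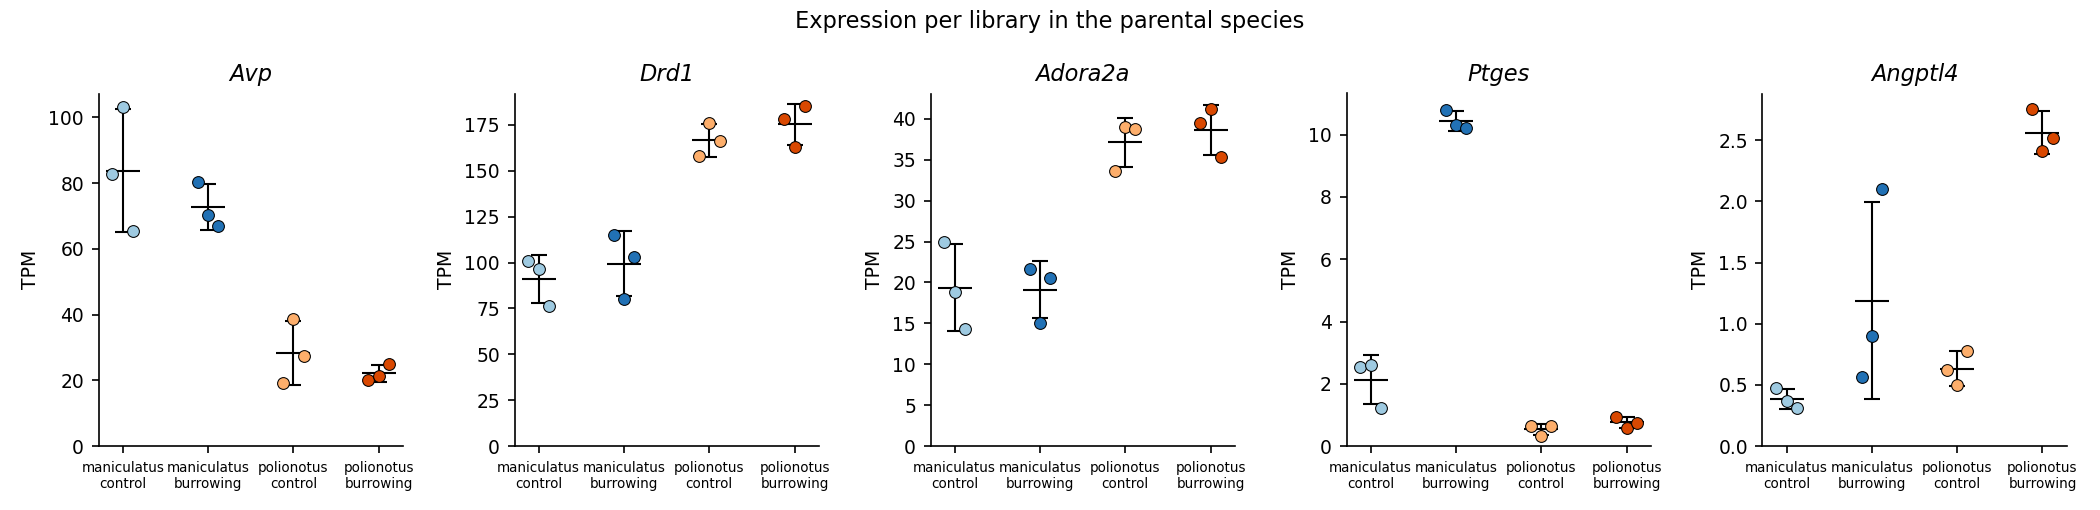
TPM (vertical axis) of 5 genes in each parental library, with the group mean and SD (n = 3 libraries per group) as bars. Avp was lower, and Drd1 and Adora2a were higher, in all 6 *P. polionotus* libraries than in all 6 *P. maniculatus* libraries; Ptges stood at 10.4 TPM on average in burrowing *P. maniculatus*, and Angptl4 was higher after the burrowing trial in both species without passing the test.

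Of 14366 genes tested, 7529 were called, 4688 higher and 2841 lower in *P. polionotus*; 672 of them differed by over 1 log2. The balance depended on the scaling: quantile normalization gave 3826 higher and 3857 lower, and median scaling 3884 and 3775. The largest differences were near presence against absence. Mep1b, a meprin metalloprotease subunit, was at 615 ± 81.5 TPM in *P. maniculatus* and 0.423 ± 0.0786 TPM in *P. polionotus* (-8.75, SE 0.08), and the actin-like gene Actbl2, which has near-identical paralogs, at 1.21 ± 0.38 and 610 ± 156 TPM (8.1, SE 0.14). Iscu, the scaffold of iron-sulphur cluster assembly, was at 362 ± 37.5 TPM in *P. polionotus* and 40.8 ± 2.57 TPM in *P. maniculatus* (3.11, SE 0.07), while Atp6v1f, a subunit of the vacuolar proton pump, was at 6.56 ± 0.863 and 139 ± 13.9 TPM (-4.21, SE 0.09). Higher in *P. polionotus* were also Krt20 (3.53), Ct55 (3.2), the ascorbate transporter Slc23a1 (3.06), Nemp2 (2.68), Arl11 (2.57) and the meiotic cohesin Rec8 (2.48). Lower were Ankrd26 (-4.74), the helicase Ddx11 (-3.61), Lypd3 (-3.48), the apolipoprotein Apoa4 (-3.18), the bile acid ligase Slc27a5 (-3.11) and the aldehyde dehydrogenase Aldh3a1 (-3.05). Adjusted p of these 16 genes ranged up to 0.000723. Whether reads of both species aligned equally well is not given in the sources used here.

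Among the lists, genes of striatal medium spiny neurons had 14 members higher and 1 lower in *P. polionotus* of 25 tested (15 called when adjusted over the list alone), and genes of oligodendrocyte precursors 11 higher and 0 lower of 15 (11 when adjusted over the list alone). With quantile normalization the striatal list had 12 higher and 1 lower and the precursor list 9 and 0. Neither list passed camera against the other genes (adjusted p = 0.183 and 0.0798). Locomotor behaviour genes, the group the series is about, had 33 members higher and 21 lower of 122 tested (51 called when adjusted over the list alone), a median of 0.06 log2 and a camera adjusted p of 0.995; with quantile normalization 30 were higher and 32 lower. None of the 46 lists passed camera, and 17 moved on balance 1 way by fry.

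In control animals, Hox genes of the hindbrain and spinal cord were lower in *P. polionotus*. Hoxb5 was at 3.08 ± 3.08 against 8.47 ± 1.05 TPM (SD, n = 3 each; -1.51, SE 0.43, adjusted p = 0.0167), Hoxd4 lower by a log2 fold change of -0.99 (SE 0.25, adjusted p = 0.0102) and Hoxb4 by -0.75 (SE 0.23, adjusted p = 0.0219). Of 19 tested spinal cord and hindbrain patterning genes, 12 were lower and 0 higher (13 lower when adjusted over the list alone; camera adjusted p = 0.000209), and the call was lost with an estimated correlation (adjusted p = 0.979). Choroid plexus and ependymal genes had 7 members lower and 0 higher of 19 (7 when adjusted over the list alone; camera adjusted p = 0.21), and only these 2 lists passed Fisher's test of higher against lower called members (adjusted p = 6.31e-05 for the hindbrain list and 0.0088 for this one). The hindbrain list mean in the polionotus control libraries was 1.85, 0.9 and 1.34 on the log2 scale, against 1.97 to 2.21 in maniculatus controls. Of 15 oligodendrocyte precursor genes, 9 were higher and 0 lower (9 when adjusted over the list alone; camera adjusted p = 0.0334), again lost with an estimated correlation (adjusted p = 0.979). Among them were the proteoglycan Vcan (0.43, SE 0.07), Cacng4 (0.47, SE 0.07) and Lhfpl3 (0.51, SE 0.08). Avp (-1.56), Drd1 (0.87) and Adora2a (0.94) differed in control animals as in the mean of both trials, as did the lectin Lgals12 (2.83) and Zmynd15 (-3.11).

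**Figure D2:**
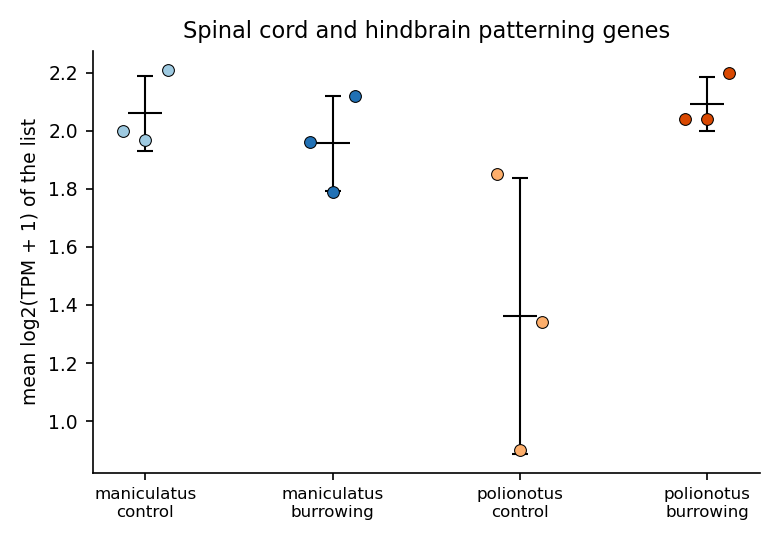
Mean log2(TPM + 1) (vertical axis, not starting at 0) of 19 spinal cord and hindbrain patterning genes in each parental library, with group mean and SD (n = 3). The polionotus control libraries lie at 0.9, 1.34 and 1.85, and the other libraries between 1.79 and 2.21.

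In control animals 5696 genes were called, 3843 higher and 1853 lower (2827 and 2852 with quantile normalization, 2886 and 2776 with median scaling). Without the polionotus control replicates 2 and 3, low in the hindbrain list and left out after that was seen, 2733 genes were called; the Hox genes above and Adora2a (0.8, adjusted p = 0.0723) no longer passed. That left 1 library in the group, with its spread taken from the other groups, so lost power is mixed with the removal: without replicates 1 and 2 or 1 and 3, also chosen after seeing the data, 3282 and 5039 genes were called, and of Hoxb5, Hoxd4, Hoxb4 and Adora2a only Hoxb4 did not pass, in the first (adjusted p = 0.071). With the hindbrain list as a covariate 2440 genes were called, and Adora2a (0.78, adjusted p = 0.079) again did not pass. Hoxb4 also lost its call without maniculatus control replicate 2 or 3 (adjusted p = 0.0501 and 0.0615) and, like Hoxb5, when only the groups compared were fitted (0.0645 and 0.0698).

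After the burrowing trial the hindbrain list did not stand apart: 1 of its 19 members was higher in *P. polionotus* and 0 were lower (0 when adjusted over the list alone), with a median of 0.06. Of 15 oligodendrocyte precursor genes 5 were higher and 0 lower (8 when adjusted over the list alone; median 0.3, camera adjusted p = 0.152). Avp (-1.67, SE 0.22), Drd1 (0.83, SE 0.13) and Adora2a (0.99, SE 0.18) differed here too. Il33, an alarmin made by glia, was at 23 ± 8.12 TPM in *P. polionotus* and 2.56 ± 0.187 TPM in *P. maniculatus* (2.69, SE 0.68, adjusted p = 0.0107); 1 maniculatus control library, replicate 3, held 33.7 TPM against 2.77 in the other controls. Ccer1 was lower in *P. polionotus* (-2.98, SE 0.32, adjusted p = 5.32e-05). In all, 4901 genes were called, 2876 higher and 2025 lower, and 0 of 46 lists passed camera.

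The next comparisons ask what a bout of digging changed. In *P. maniculatus*, Ptges, the inducible synthase of prostaglandin E, was at 2.13 ± 0.777 TPM in control animals and 10.4 ± 0.288 TPM in burrowing animals (SD, n = 3 different animals each, log2 fold change 1.91, SE 0.17, adjusted p = 0.0036). It was the only gene called of 14366, with 291 at an unadjusted p under 0.05 where 718 would be expected by chance. In *P. polionotus* it was between 0.331 and 0.945 TPM in all 6 libraries. Coq4 of coenzyme Q synthesis (-0.46, SE 0.06, adjusted p = 0.0933) and the methyltransferase Ntmt1 (-0.52, SE 0.08, adjusted p = 0.254), which share a chromosome with Ptges in assembly GCF_049852395.1, did not pass. Nor did the kinase Nuak2 (0.34, SE 0.08), Pcdhb2 (0.63, SE 0.15), Hddc3 (-0.22, SE 0.06) or Angptl4 (0.6, SE 0.2). Fos, an immediate early gene of active neurons, stood at 126 ± 39.3 TPM after burrowing and 123 ± 21.3 TPM in controls, and the glucocorticoid-induced kinase Sgk1 at 208 ± 89.2 and 170 ± 26.2 TPM. Of 46 lists, 21 passed camera, 7 of them upward. Oligodendrocyte and myelin genes had a median of -0.08 over 27 members (camera adjusted p = 2.28e-05), with Mbp at -0.18 (SE 0.08), Ugt8 at -0.22 (SE 0.12) and Cldn11 at -0.15 (SE 0.08). Glucocorticoid-responsive genes had a median of 0.14 over 19 (camera adjusted p = 0.0141), with Arrdc2 at 0.45 (SE 0.24) and Klf9 at 0.14 (SE 0.08). Neither list had a called member, over all genes or when adjusted over the list alone, and both calls were lost with an estimated correlation (adjusted p = 0.482 for each). Marker lists of other regions and cells passed too: cerebellar, hindbrain, thalamic, and choroid plexus and ependymal genes downward (camera adjusted p = 0.00352, 0.00703, 0.0146 and 0.0146) and excitatory cortical and hippocampal neuron genes upward (0.0201), all lost with an estimated correlation (adjusted p = 0.483 to 0.52). Whether such lists follow a response or different shares of brain regions in the libraries was not tested. The Ptges call ended with a pseudocount of 0.1 (adjusted p = 0.0859) and when only the groups compared were fitted (0.4). Without maniculatus burrowing replicate 2, control replicate 1 or control replicate 2 the count was 4, 6 and 3. Of 10 splits of these animals, the real one among them, 7 gave as many calls, and the highest other count was 5. Of the 27 genes with the smallest p, 22 could be placed. They made 10 pairs within 25 genes of each other, against a mean of 0.91 in random sets. The Ptges call therefore cannot be credited to the trial.

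In *P. polionotus* limma called 0 genes after the trial, with 446 at an unadjusted p under 0.05 and 718 expected by chance. The smallest p-values belonged to the kinase Nuak2 (0.48, SE 0.08), the adhesion protein Igdcc4 (0.31, SE 0.05) and Angptl4, a secreted inhibitor of lipoprotein lipase, at 2.56 ± 0.177 TPM after burrowing and 0.634 ± 0.14 TPM in controls (1.13, SE 0.2), each with an adjusted p of 0.648, and on the other side to Hexim2 (-0.77, SE 0.17), the death ligand Tnfsf10 (-0.69, SE 0.15) and the fatty acid receptor Ffar3 (-1.03, SE 0.23), each with an adjusted p of 0.998. Glucocorticoid-responsive genes had a median of 0.14 over 19 members (camera adjusted p = 2.49e-09), with Pdk4, which limits glucose oxidation, at 74.9 ± 8.17 against 37.2 ± 5.43 TPM (0.99, SE 0.25) and Ddit4 at 0.35 (SE 0.12); 0 members passed over all genes and 2 when adjusted over the list alone. The list call was lost with an estimated correlation (adjusted p = 0.0668). Immediate early genes had a median of 0.14 over 33 members (camera adjusted p = 5.32e-05; adjusted p = 0.83 with an estimated correlation), with Csrnp1 at 0.49 (SE 0.12), Klf4 at 0.67 (SE 0.27) and Maff at 0.53 (SE 0.22), and with Fos at 0.22 (SE 0.33); 0 passed when adjusted over the list alone. Sgk1 stood at 0.5 (SE 0.28). Choroid plexus and ependymal genes had a median of 0.1 over 19 members (camera adjusted p = 0.000448; adjusted p = 0.83 with an estimated correlation), of which 0 passed when adjusted over the list alone. The hindbrain list had a median of 0.66 (camera adjusted p = 3.25e-23; adjusted p = 0.118 with an estimated correlation) with Hoxa5 at 1.7 (SE 0.4), Hoxa4 at 1.29 (SE 0.36) and Hoxd4 at 0.94 (SE 0.25), and 13 members higher when adjusted over the list alone while the lowest list means, 0.9 and 1.34, belonged to polionotus control replicates 2 and 3. Of 46 lists, 7 passed camera, 6 of them upward. Besides those above, these were heat shock and chaperone genes, dopaminergic neuron genes, and excitatory cortical and hippocampal neuron genes. Without polionotus burrowing replicate 3 and without control replicate 1 the count of calls was 1 and 2, with Hoxa5 called in the latter (2.25, adjusted p = 0.0269), and with no expression filter it was 3.

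The difference between the responses of the species was tested directly. For Ptges the response in *P. polionotus* was smaller by a log2 difference of -1.7 (SE 0.24), the smallest p of all genes, but it did not pass (adjusted p = 0.296). Pcbp1 (-1.52, SE 0.35), Pex16 (-0.41, SE 0.09), Coq4 (0.44, SE 0.09), Ntmt1 (0.56, SE 0.12) and Fam166b (0.78, SE 0.2) followed, each with an adjusted p of 0.992. limma called 0 genes, with 415 at an unadjusted p under 0.05 and 718 expected by chance. Ptges passed with a pseudocount of 5 (-1.06, adjusted p = 0.00377) and without maniculatus control replicate 3 (-1.48, adjusted p = 0.0331), and without maniculatus control replicate 1 the count was 2. Of 46 lists, 11 passed camera; the hindbrain list had a median of 0.7 (adjusted p = 3.43e-22; adjusted p = 0.266 with an estimated correlation), with Hoxa5 at 1.82 (SE 0.56), Hoxa4 at 1.78 (SE 0.51) and Hoxa2 at 1.08 (SE 0.35) and 5 members higher when adjusted over the list alone.

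Averaged over both species, Ptges was again the only gene called (1.05, SE 0.12, adjusted p = 0.0408) with 1.91 in *P. maniculatus* and 0.2 (SE 0.17) in *P. polionotus*; 296 genes had an unadjusted p under 0.05. Nuak2 was at 3 ± 0.229 against 2.02 ± 0.298 TPM (SD, n = 6 each; 0.41, SE 0.05, adjusted p = 0.0957) and Angptl4 at 1.88 ± 0.916 against 0.509 ± 0.17 TPM (0.86, SE 0.14, adjusted p = 0.338); Nuak2 passed without the trend (adjusted p = 0.0453) and Angptl4 without maniculatus burrowing replicate 3 (0.72, adjusted p = 0.0412). Coq4 (-0.24, SE 0.04), Ffar3 (-0.8, SE 0.16) and Tnfsf10 (-0.49, SE 0.11) led the other direction without passing. Glucocorticoid-responsive genes had a median of 0.19 (camera adjusted p = 8.09e-10; adjusted p = 0.0519 with an estimated correlation), with Pdk4 at 0.64 (SE 0.17) and Ddit4 at 0.27 (SE 0.09) and 2 members passing when adjusted over the list alone. Immediate early genes had a median of 0.11 (camera adjusted p = 6.09e-05; adjusted p = 0.67 with an estimated correlation), with Csrnp1 at 0.34 (SE 0.09), Fosb at 0.47 (SE 0.18) and Maff at 0.43 (SE 0.16). Oligodendrocyte and myelin genes had a median of -0.07 (camera adjusted p = 2.62e-06; adjusted p = 0.635 with an estimated correlation), with Mag at -0.21 (SE 0.06), Mbp at -0.15 (SE 0.06) and Opalin at -0.26 (SE 0.1). The hindbrain list had a larger median, 0.3 (camera adjusted p = 1.08e-08; adjusted p = 0.635 with an estimated correlation), and thalamic genes had one of -0.06 (camera adjusted p = 0.0202; adjusted p = 0.635 with an estimated correlation). None of these last 4 lists had a member passing when adjusted over the list alone. Fos (0.12, SE 0.24) and Sgk1 (0.35, SE 0.2) did not pass. The Ptges call ended with quantile or median scaling (adjusted p = 0.078 and 0.0521), with a pseudocount of 0.1 (0.265), and without any 1 of the 3 maniculatus burrowing libraries (0.0683 to 0.173) or of the 6 polionotus libraries (0.0694 to 0.199); without maniculatus control replicates 1 and 2 the counts were 3 and 2.

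In the F1 hybrids edgeR called 0 of 11928 genes after the trial, with 90 at an unadjusted p under 0.05 where 596 would be expected by chance. DESeq2 called 2, both lower: Tle6, a Groucho-family corepressor, at 4.39 ± 2.27 CPM after burrowing and 24 ± 4.39 CPM in controls (SD, n = 3 each; -2.45, SE 0.41 in edgeR; DESeq2 adjusted p = 5.1e-06), and LOC102922681, a gene without a symbol named here after its value was seen (-0.85, SE 0.19 in DESeq2; DESeq2 adjusted p = 0.0312). Angptl4 was at 3.48 ± 1.28 against 1.2 ± 0.118 CPM (1.55, SE 0.32, edgeR adjusted p = 0.965), with Syt16 at 0.53 (SE 0.12), Kdelr3 at 0.68 (SE 0.21), Ccdc175 at -1.23 (SE 0.28) and Rab20 at -0.88 (SE 0.25). Chaperone genes had a median of 0.18 over 16 members (camera adjusted p = 4.54e-05; adjusted p = 0.297 with an estimated correlation; fry adjusted p = 0.0179), with Hsph1 at 654 ± 24 against 522 ± 32.7 CPM (0.33, SE 0.11), Pdia4 at 0.31 (SE 0.12) and Manf at 0.49 (SE 0.22). Immediate early genes had a median of 0.25 over 28 members (camera adjusted p = 1.68e-05; adjusted p = 0.941 with an estimated correlation), with Fos at 38.5 ± 6.17 against 20.8 ± 9.97 CPM (0.87, SE 0.32), Homer1 at 0.38 (SE 0.19) and Dusp6 at 0.23 (SE 0.13). No member of either list passed over all genes or when adjusted over the list alone. Of 42 lists, 4 passed camera, 3 of them upward. The others were interferon-stimulated genes and complex I subunit genes. Sgk1 stood at 0.1 (SE 0.14). Control replicate 3 held 53906964 counts, more than the other 2 control animals together.

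Within a hybrid both alleles share 1 cellular environment, so the allele comparison addresses differences that act in cis. Genes on the X are an exception, because the hybrids were males with 1 X. Any effect of the parent of origin is included, because all hybrids are labelled as the same cross. So is any bias in how reads were aligned or given to an allele, which is not given in the sources used here. Adora2a had 59.9% ± 2.29 of its counts on the polionotus allele (SD, n = 6 animals; 0.58, SE 0.06, adjusted p = 0.000348) and Drd2 57.2% ± 2.9 (0.42, SE 0.07, adjusted p = 0.00236). Drd1 was at 50.9% ± 0.822 (0.05, SE 0.04), Tac1 at 51.3% ± 1.34 (0.08, SE 0.04), Penk at 53.7% ± 4.54 (0.22, SE 0.1), Avp at 44.8% ± 10.9 (-0.28, SE 0.25), Oxt at 53.1% ± 4.91 (0.17, SE 0.11) and Slc6a3 at 56.3% ± 14.7 (0.4, SE 0.38), none of which passed. Avp was at 23.3% (Wilson interval 16.5 to 31.7) in control replicate 2, without which its value was -0.04, and Slc6a3 at 85.3% (81 to 88.7) in burrowing replicate 3, without which it was 0.04. The largest imbalances left almost no counts on 1 allele, except that Timm10, at 91.6% ± 18.7, was at 53.4% (Wilson interval 51.1 to 55.7) in burrowing replicate 2. On the polionotus side these were Ndrg2, an astrocyte gene, at 99.7% ± 0.0392 (8.59, SE 0.1), Timm10 (6.24, SE 1.27), Rilpl1 (5.75), Cttn (5.67), Copz1 (5.43), Cacng7 (5.42), Casc4 (5.39) and Maneal (5.32). On the maniculatus side were the synaptic vesicle protein Syp at 0.0148% ± 0.00494 (-12.68, SE 0.2), the myelin-associated Gpm6b (-12.01), Gprasp1 (-11.72), the kinase Braf (-8.81), Ubl4a (-8.12), Med12 (-7.99), Dnajc12 (-7.69) and Fopnl (-6.06). Of the fixed list of genes that are X-linked in mouse, 8 were tested. Of these, 7 were lower on the polionotus allele and 0 higher (7 when adjusted over the list alone, median -4.22, camera adjusted p = 1.19e-07, adjusted p = 0.485 with an estimated correlation), Syp, Gpm6b and the deubiquitinase Usp9x (-5.02, SE 0.09) among them. In males the direction of this list depends on which parent gave the X, so the list is no test of cis differences. Of 36 tested genes placed on the X in assembly GCF_049852395.1, 20 had over 10% of counts on the polionotus allele.

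Of 11928 genes 6641 were called, 4074 higher and 2567 lower on the polionotus allele. TMM scaling per allele column moved the median of all genes from 0.107 to -0.071 and gave 2786 higher and 4215 lower, so directions of small differences hold only relative to that shift; Drd1 was then at -0.13, Tac1 at -0.1 and Oxt at -0.01. Locomotor behaviour genes had 29 members higher and 26 lower of 110 tested (50 called when adjusted over the list alone; camera adjusted p = 0.987), and 21 higher and 49 lower under TMM. Adora2a did not pass without the animal as a block (adjusted p = 0.11). A binomial test in every animal called 3137 genes.

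Set beside each other, the species difference and the allele difference could be compared for 9989 genes tested in both tables, which come from different animals and were normalized separately. Called in both were 3200 genes, of which 82.7% had the same sign: 1770 were higher on the polionotus side in both and 875 lower in both, where independent calls would give 1135 and 399. Opposite signs were found for 273 and 282 genes, against 714 and 634. The balance depended on the scaling: with quantile normalization of the species libraries and TMM per allele column, chosen after seeing the data, 76.6% of 3246 genes had the same sign, 1005 higher and 1481 lower in both, against 610 and 956 for independent calls, and with median scaling and TMM 76.5%, 1021 higher and 1448 lower. Across genes, which are not independent replicates, Pearson's r was 0.309 and Spearman's rho 0.363. Whether a bias of alignment shared by both tables adds to the same signs was not tested. Krt20 (species 3.53, allele 4.26), Slc27a5 (-3.11 and -3.9), Lgals12 (2.34 and 4.2) and Adora2a (0.96 and 0.58) differed the same way in both. Atp6v1f (-4.21 and 0.09), Aldh3a1 (-3.05 and -0.05), Avp (-1.62 and -0.28, or -0.04 without hybrid control replicate 2) and Drd1 (0.85 and 0.05) differed between the species and had allele values that did not pass. Ndrg2 (-0.03 and 8.59) and Braf (-0.22 and -8.81) showed the reverse arrangement, a near-complete imbalance of the alleles with a small difference between species. Syp (0.08 and -12.68) had like values. It is X-linked in mouse and the hybrids were males, so its value is not read as a difference between alleles. Vcan was higher in *P. polionotus* (0.38) and lower on its allele (-0.18). Counts of 2000 genes called only between species and 2336 only between alleles come from separate tests, and the difference between both values was not tested per gene.

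**Figure D3:**
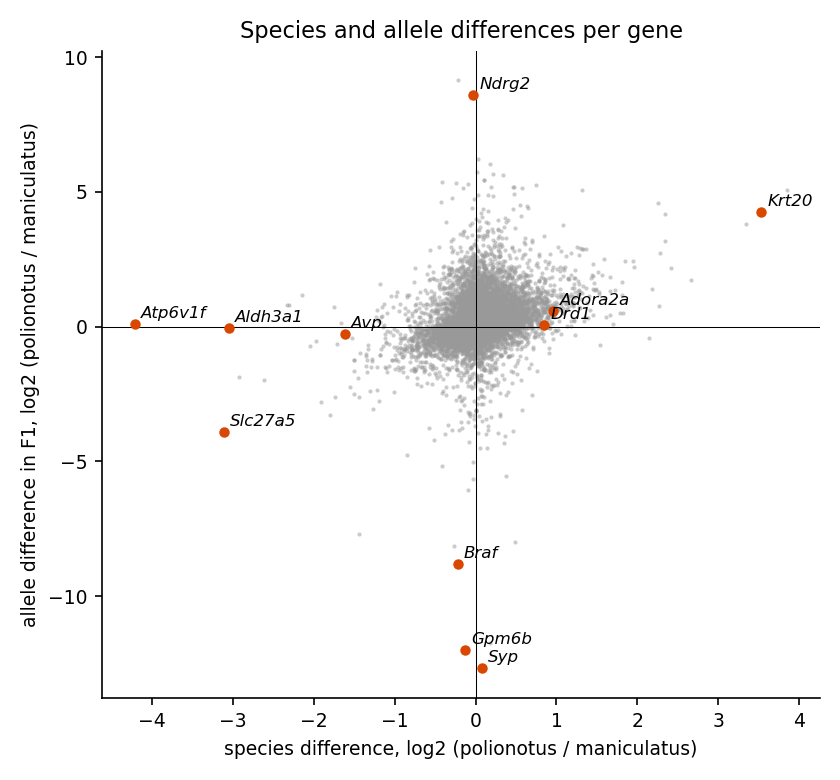
Species difference (horizontal axis, log2 of polionotus over maniculatus) against allele difference in the F1 (vertical axis, same scale) for the 9989 genes tested in both tables, with named genes in orange. Krt20 and Slc27a5 lie on the diagonal side, Atp6v1f, Aldh3a1 and Avp near the horizontal axis, and Ndrg2, Syp, Gpm6b and Braf near the vertical axis. Syp and Gpm6b are X-linked in mouse and the hybrids were males, so these values are not read as differences between alleles.

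Whether the allele difference differed between the trials was tested between the 3 control and the 3 burrowing hybrids, which are different animals. Ubxn6, a cofactor of the p97 ATPase, went from 47.5% ± 2.05 of counts on the polionotus allele in controls to 98.2% ± 0.526 after burrowing (SD, n = 3 each; 5.86, SE 0.22, adjusted p = 0.00129), the lipid droplet protein Plin3 from 65.4% ± 1.61 to 96.9% ± 1.19 (4.15, SE 0.3, adjusted p = 0.0161), and the anchoring protein Akap8l from 47.4% ± 1.9 to 90.6% ± 0.455 (3.41, SE 0.09, adjusted p = 0.000563). Tle2 (2.4, SE 0.21), Akap8 (2.36, SE 0.16) and Ankrd24 (2.33, SE 0.23) followed. Dcaf5, a ubiquitin ligase adaptor, went from 15.8% ± 0.277 to 48.6% ± 0.68 (2.33, SE 0.07, adjusted p = 0.000594). Of 11928 genes, 27 were called, 26 of them with a higher polionotus share after burrowing, and 266 had an unadjusted p under 0.05 where 596 would be expected by chance. Of the 27 genes, 22 had a place in the reference gene order. They formed 48 pairs within 25 genes of each other, on 4 chromosomes, against a mean of 1.1 in random sets. Of 10 splits of these animals, the real one among them, 4 gave as many calls, and 1 gave 221. The calls therefore cannot be credited to the trial. Fos (-0.31, SE 0.28) and Sgk1 (0, SE 0.06) did not pass, and 0 of 42 lists passed camera. DESeq2 called 60 genes, all 27 among them. Without burrowing replicate 1 or 3 the count was 60 and 43, and without control replicate 2 or 3 it was 10 and 73, with 43 lower in the last. Plin3, Tle2, Akap8 and Ankrd24 lost their calls without 1 or more of the animals.

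**Figure D4:**
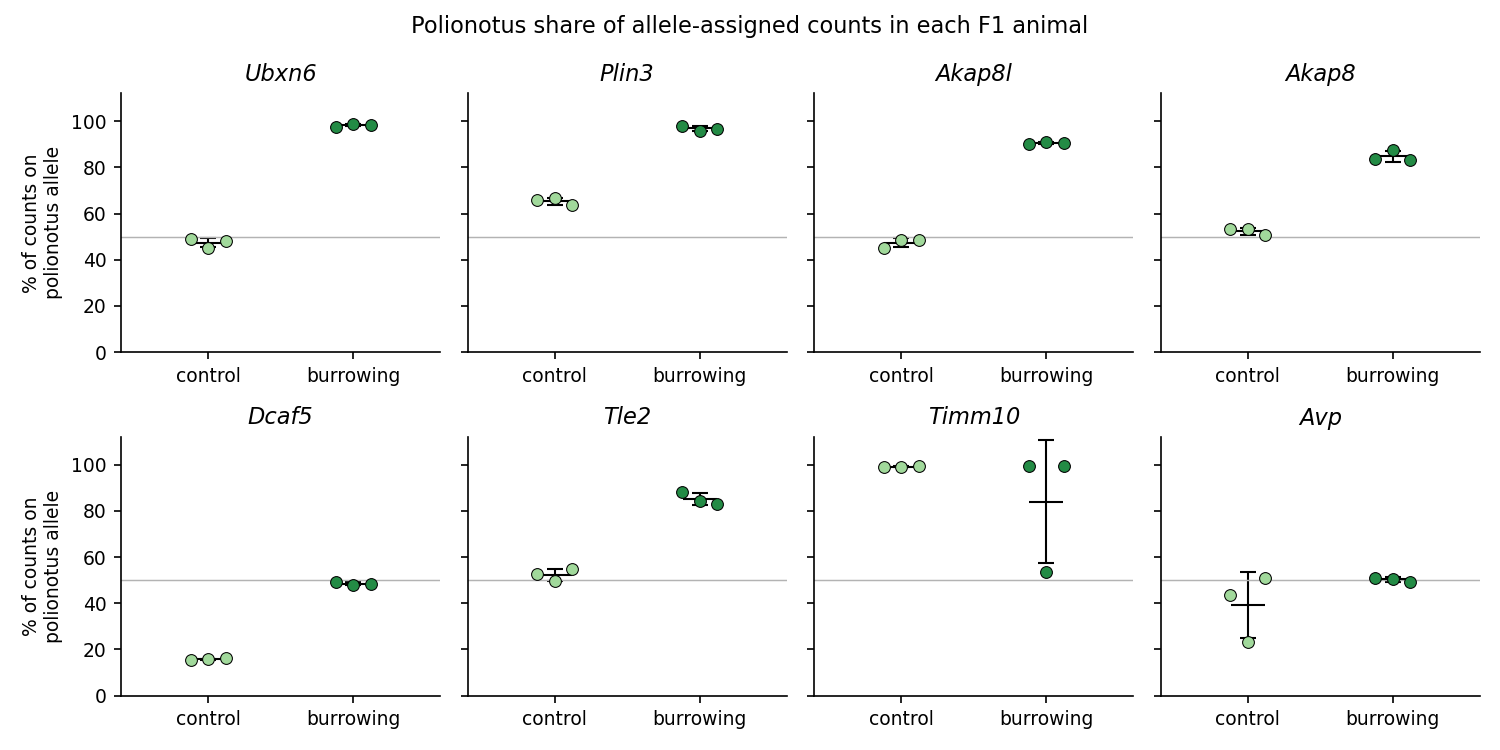
Percent of allele-assigned counts on the polionotus allele (vertical axis) for 8 genes in each F1 animal, with group mean and SD (n = 3 different animals per trial). The grey line marks 50%. Ubxn6, Plin3, Akap8l, Akap8, Dcaf5 and Tle2 separate by trial with little spread within groups, Timm10 is at 53.4% (Wilson interval 51.1 to 55.7) in 1 burrowing animal and at 99% or above in the others, and Avp is at 23.3% (16.5 to 31.7) in 1 control animal.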

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

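Tests chosen only after the result was seen were those of inherited haplotypes, of a constant species difference and a trial response in the hindbrain genes, and of X linkage and a matching species difference for 1-sided alleles. The other tests were chosen before. Limits after a median in this section treat genes as independent and do not cover spread between animals.

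In 27 genes the allele difference of the hybrids differed between the trials, among them Ubxn6 (log2 difference 5.86), Plin3 (4.15), Akap8l (3.41), Tle2 (2.4), Akap8 (2.36), Ankrd24 (2.33) and Dcaf5 (2.33). Of these genes 22 could be placed, and they made 48 pairs within 25 genes of each other, against a mean of 1.1 and a maximum of 7 in 10000 random sets (permutation p = 1e-04, the smallest these sets can give). A cis response to the trial would recur as a difference between the parents' responses. The median of that difference over 21 genes, signed by the allele effect, was -0.09 (limits -0.17 to 0). The allele effect had a median size of 2.22, so this argues against a cis response, although genes that neighbour each other are not independent. The top 27 genes of each of the other 9 splits of the 6 animals made 11 to 244 pairs, so the values are consistent with chromosome segments that differ between animals, such as segments inherited in different versions from parents that were not fully inbred. This stays a hypothesis, since no genotype was analysed here.

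In the polionotus control libraries the spinal cord and hindbrain genes had means of 1.85, 0.9 and 1.34, against 1.79 to 2.21 elsewhere. A constant species difference is argued against, since the list median was 0.06 (limits -0.07 to 0.23) in burrowing animals and -0.61 (-1 to -0.33) in control animals. Different amounts of caudal tissue in the dissections are a candidate explanation: deviations from group means of 13 Hox genes and of the 6 other members correlated over the 12 libraries (Pearson r = 0.748, exact permutation p = 0.00309; Spearman rho = 0.839, p = 0.00849; r = 0.757 without the 2 farthest libraries). Choroid plexus and ependymal genes had 7 of 19 members lower and 0 higher in the same control comparison (Fisher adjusted p = 0.0088); whether they vary with the caudal genes was not tested. A response to the trial cannot be told apart from it, because 3 against 3 libraries cannot give an exact permutation p under 0.1, the value found.

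Of the genes with over 95% of counts on 1 allele, 20 lay on the maniculatus side and 23 on the polionotus side. On the maniculatus side 15 of the 20 could be placed, and 8 of these are on the X in assembly GCF_049852395.1 (Fisher's exact p = 6.84e-17 over genes, against 36 tested X genes). Males that carry a maternal X from *P. maniculatus* would give this. The smallest count in any column was 2, so an X gene read from 1 allele alone would be missing, and the 36 are those with counts on both. Of them, 20 had over 10% of counts on the polionotus allele. In males with 1 X this points to reads given to the wrong allele or genes wrongly placed, which were not told apart. On the polionotus side 22 could be placed and 0 of them are on the X, so X linkage does not account for these 22. A cis difference of that size is argued against: 31 genes not placed on the X had a median species difference, signed by the allele, of 0.16 (limits 0.01 to 0.41) against a median allele difference of 5.19, and 24 of them differed by less than 0.5 between species. For the genes not placed on the X, reads of 1 allele lost or given to the other remain open. Their median of hybrid counts relative to parental TPM differed from that of other genes by -0.62 (limits -1.93 to 0.04), which excludes neither. Effects of the parent of origin were not tested.

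Of 76 groups of 6 samples, 11 held a sample far from the others, where 3.8 would be expected by chance for independent groups. The groups share libraries and several of these values come from the same library, so the counts are no test of an excess. Among parental libraries, Actbl2 was at 917 TPM in polionotus control replicate 2 (464 to 576 in the others), and Slc6a3 at 6.18 TPM in polionotus burrowing replicate 3 (4.33 to 4.75). In *P. maniculatus*, Ct55 was at 1.3 TPM (0.412 to 0.726) and Aldh3a1 at 7.58 TPM (57.2 to 66.3) in control replicate 3, and Apoa4 at 22.3 TPM in control replicate 2 (6.55 to 11.8). Among hybrids, in burrowing replicate 2 the polionotus share was 53.4% for Timm10 (Wilson interval 51.1 to 55.7; 99 to 99.5 in the others), 99.1% for Cacng7 (98.7 to 99.3; 97.2 to 97.4) and 98.6% for Maneal (98.2 to 98.9; 97.1 to 97.6). It was 0.856% for Dnajc12 in burrowing replicate 1 (0.451 to 1.62; 0.294 to 0.467 in the others) and 85.3% for Slc6a3 in burrowing replicate 3 (81 to 88.7; 44.1 to 56.2). For Avp it was 23.3% in control replicate 2, from 116 counts (16.5 to 31.7; 43.8 to 51.1 in the others).

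Other splits of the same samples were counted for each comparison. For the species difference 1 of 100 splits, the real one with 7790 genes in a test of both species without the trials, gave as many genes (highest other 1). For the allele difference it was 1 of 32 (6641 genes, highest other 38), so chance is an unlikely source of either count. Splits that mix the species or swap alleles carry the real difference as spread, so their low counts do not measure its size. Chance is not excluded for the response over both species (49 of 100, 1 gene, highest other 4). Where 0 genes were called every split gives as many, so the count says nothing about chance: this holds for the species by trial interaction (100 of 100 splits, highest other 6) and the responses in *P. polionotus* (10 of 10, highest other 3) and in the hybrids (10 of 10, highest other 1). With 10 splits a share under 0.05 cannot be reached: as many genes came from 1 split in control animals (5696 genes, highest other 0), 1 in burrowing animals (4901, highest other 0) and 7 for the response in *P. maniculatus* (1 gene, highest other 5). For the allele by trial term 4 of 10 splits gave as many as the real 27 genes, and 1 gave 221, which points to a structure of these animals other than the trial.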

How the results depend on the processing

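Of 184 alternative values of comparisons and lists, 137 stayed within 1.5 times the count reported, or within 5 points for a share, and 47 did not; of 2484 alternative values of named genes, 2402 kept direction and side of the threshold, 55 lost a call, 10 gained one and 17 changed sign. Leaving out 2 polionotus control libraries, taking the hindbrain list as a covariate and setting species against alleles under other scalings were chosen after seeing the data. The species difference gave 6819 to 7510 genes without each library in turn. In control animals 2733 genes were called without the 2 libraries low in hindbrain genes (2599 shared), which leaves 1 library in that group, 3282 and 5039 without the other pairs of the group, and 2440 with the covariate (2268 shared). The response in *P. maniculatus* gave 0 genes with a pseudocount of 0.1, with a mean of at least 5 TPM, which removes Ptges, and with only the groups compared, and 1 to 6 without each library. In *P. polionotus* there were 3 with no filter and 0 to 2 without each library. The interaction gave 1 with a pseudocount of 5, 1 with no filter and 0 to 2 without each library. Over both species there were 0 with a replicate block, a pseudocount of 0.1, a mean of at least 5 TPM, quantile normalization, median scaling, without the low libraries and with the covariate, 2 with no filter and 2 without the trend, and 0 to 3 without each library. In the hybrids DESeq2 gave 2 genes for the trial, where leaving out each animal gave 0. For the allele difference in F1 hybrids a binomial test per animal gave 3137 genes, and leaving out each animal 5707 to 6395. The allele by trial term gave 60 with DESeq2, 2 with a replicate block on log ratios (adjusted p = 0.0738 for Ubxn6 and 0.0508 for Dcaf5) and 10 to 73 without each animal. Of 56 list calls, 0 held with an estimated correlation and 32 calls were found by camera with only the members of at least 5 TPM or 100 counts on average. The share of genes with the same sign between species and alleles was 76.6% with quantile normalization and 76.5% with median scaling, both with TMM per allele column. Signs changed for values near 0: Tac1 between species was 0 with the covariate and -0.1 to 0.01 without each library. Fos in *P. maniculatus* was -0.02 with quantile normalization, -0.01 with median scaling, -0.04 with the covariate and -0.22 to 0.21 without each library, Sgk1 there -0.1 to 0.57, Fos in *P. polionotus* -0.17 to 0.52 and Fos over both species -0.08 to 0.27. With TMM per allele column Drd1 was -0.13, Oxt -0.01, Tac1 -0.1 and the allele by trial value of Sgk1 0.04, which was -0.02 to 0.03 without each animal. Apart from the filter that removes Ptges, the cause was not tested. Filters of at least 1 count removed no tested gene and so tested nothing. The labels do not say that replicate numbers pair the samples; control and burrowing libraries with the same number were closer than any others in 3 of 3 cases in *P. maniculatus* and for hybrid allele ratios, in 1 of 3 for hybrid log2 CPM and in 0 of 3 in *P. polionotus*, a hint from the data and not from the design. Fits on only the groups compared do not differ for comparisons that use all groups. Simulated changes of 0.5 log2 between alleles were recovered in 6.1% of genes.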

Other observations

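Tests of the glucocorticoid and immediate early lists and of neighbours among maniculatus trial genes were chosen after the result was seen, as were the genes in the last paragraph.

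Angptl4, the secreted inhibitor of lipoprotein lipase, was the 1 gene of 9989 whose burrowing and control animals did not overlap, in the same direction, in *P. maniculatus*, *P. polionotus* and the hybrids (log2 values 0.6, 1.13 and 1.55). Chance separates 10% of genes with 3 against 3 animals and would give 2.5 such genes. As many came from 58 of 100 splits, up to 14, so the count gives no sign of a shared response. It does not argue against one either, because a moderate response would seldom separate all animals in all 3 kinds. Of the 50 genes with the smallest p for the trial over both species, 30 had the same sign in the hybrids, and the highest count in the other 9 splits of the hybrids was 33. Glucocorticoid-responsive genes were higher after the trial by 0.22 within species (exact permutation p = 0.01 over 400 arrangements, 0.1 adjusted over the 10 lists that had passed camera in this comparison); the smallest p the arrangements can give is 0.005, or 0.05 over 10 lists, so no list alone could pass. Immediate early genes were higher by 0.13, which many arrangements reached (exact permutation p = 0.48, adjusted 0.48). The top 27 genes of the maniculatus trial response made 10 pairs of neighbours against 0.91 in random sets (permutation p = 1e-04, the smallest the sets can give), those in the hybrids 6 (permutation p = 8e-04), and those in *P. polionotus* and over both species 3 each (permutation p = 0.06 and 0.08), so inherited segments that differ between the animals remain possible in the first 2, Ptges, Coq4 and Ntmt1 being on 1 chromosome.

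In the hybrids Ago2 had 7.18% ± 1.22 of counts on the polionotus allele (SD, n = 6) and Trappc9 11.9% ± 1.06, while the species differences were 0.16 and -0.15; all hybrids are labelled as the same cross, so effects of the parent of origin were not separated from cis effects. Il33 had 91.1% in burrowing replicate 2 (Wilson interval 89.6 to 92.4) and 33.1% to 36.3% in the other animals.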
